A study of Mus musculus with 8 samples.

How the data were processed

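Mouse spleen was profiled with a quantitative PCR plate of the TLR pathway (RT² Profiler) after 7 days of R848 or PBS. Per the sample records, RNA of 3 mice was pooled for each sample, cleared of DNA, transcribed with oligo(dT) primer and amplified with 50 ng of total RNA per reaction. Per the series' design text, Ct values above 35 or blank were set to 35, and values were normalized to *Hprt1*, *Hsp90ab1* and *Gapdh*.

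The deposited tables, 1 for each of 3 strains, give delta-Ct values on a log2 scale, in cycles, which per the file headers are the Ct of the gene minus the mean Ct of the reference genes. They also hold the authors' fold difference, a ratio of R848 over Mock. Per the series' design text the wild-type values summarise 2 independent experiments, so the 4 wild-type samples enter as 1 mean per treatment, with no SD. The strain of a table was taken from its name and the treatment from its column names. The authors' deposited fold differences were recomputed from the delta-Ct values and matched for 89 of 89 genes in each of 3 tables, within 0.01 cycles or 0.005 of a fold. The 3 reference genes' delta-Ct values summed to 0 within 0.01 in every column. All 6 delta-Ct columns were used. Another 6 columns of per-sample values, 2 to the minus delta-Ct, repeat the same information and were not used. The column for a test holds no value, and 7 control wells have none. Raw Ct values were not used here, and neither were values of the separate wild-type experiments.

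The log2 fold difference of a gene was its delta-Ct in Mock minus that in R848. The Ct cap gives each column a highest possible delta-Ct, which is 35 minus the mean reference Ct. It was 13.15 in wild-type Mock, 15.10 and 15.63 in TLR7-labelled Mock and R848, and 12.43 and 14.93 in IFNAR-labelled Mock and R848, shared by 5 to 14 genes. From it follow the reference Ct of each column and the limit of detection. In wild-type R848 only *Tlr5* stood at the highest value, 16.67, which gives an upper limit on the reference Ct alone. A fold with Mock at the cap is given as "at least" when R848 was higher, a fold with R848 at the cap likewise when it was lower, and in the remaining cases with a column at the cap the direction is called open. In the wild-type means a gene capped in only 1 of the experiments cannot be recognised. Measured directions numbered 77 genes in wild type, 78 in the TLR7-labelled pair and 69 in the IFNAR-labelled pair. The precision of a single reading is unknown, since no repeat readings were used.

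A test had been planned for wild type if values of the separate experiments were present. With 1 mean per treatment in the tables used here it was not run, and no gene carries a p-value between treatments or strains. The p-values given are for overlaps and correlations across genes. Differences between strains had been planned beside the range of the wild-type experiments and are given against their mean alone. Genes were counted at 2-fold, and differences of responses at 1 log2 unit. The 17 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. That rule names, in wild type, up to 12 genes with the highest and 12 with the lowest ratio at 2-fold or more. It names up to 8 each way in each deficient strain and in each difference between strains. *Tlr7*, *Tlr9*, *Tlr3*, *Tlr4*, *Myd88*, *Irak1*, *Cxcl10*, *Eif2ak2*, *Irf1*, *Il6*, *Tnf*, *Ifng*, *Ifnb1*, *Il10*, *Il12a*, *Il1b* and the reference genes are always given. Other list members were named as examples after their values were seen, as were the genes named between Mock columns. The lists cover receptors, adaptors, pathways, cytokines, interferon-inducible genes, stress genes, the housekeeping genes and cell types that a spleen holds. A list's median was set against 10000 random lists of the same size from the 84 genes, as a description of these samples, and no percentile was computed for lists of under 3 genes. Correlations across genes carry permutation p-values from 100000 permutations, two-sided.

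Alternatives were each reference gene alone, all 5 housekeeping genes, centring on the median gene, leaving out genes at the cap or above Ct 33, and thresholds of 1.5-fold and 3-fold. Added after seeing the data were leaving out the first 4 wells, counting known directions only and random lists matched on mean delta-Ct. Added likewise were the TLR7-labelled Mock column as a control for the other strains, and list medians and counts over known directions under each scaling. The 5-gene reference shifted log2 differences by -0.50 in wild type, -0.11 in the TLR7-labelled pair and -0.62 in the IFNAR-labelled pair. *Hsp90ab1* alone shifted them by 0.52, 0.13 and 0.40, *Hprt1* alone by -0.28, -0.17 and -0.40, and *Gapdh* alone by -0.23, 0.03 and 0.

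The calling of directions was tried on 200 simulated plates of 84 genes with 30 changed genes each and a noise SD of 0.2 cycles. Changed genes were not checked against the 2-fold threshold. No scaling error and no mean of experiments was simulated, so the percentages mainly show how many genes the cap leaves open. For wild type the direction was recovered for 92.6% of 2-fold and 93.8% of 4-fold changes. It was recovered for 93.4% and 94.7% in the TLR7-labelled design and for 85.0% and 87.2% in the IFNAR-labelled design, the rest being nearly all open because of the cap. Of 89 gene symbols, 86 matched a mouse gene table (GRCm38.p6) directly and 3 through synonyms. The tables name no genome build, and no coordinates are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.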

Results

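Transcript levels were measured in whole mouse spleen after 7 days of treatment with R848 (resiquimod), a small-molecule agonist of the endosomal receptor TLR7, or with PBS (Mock). R848 was given at 1 mg per kg per day. Mice were C57BL/6 wild type, or were labelled as lacking TLR7 or the type I interferon receptor (IFNAR). The series holds 8 samples in 6 groups, each sample being RNA pooled from 3 mice. Wild-type mice were sampled in 2 experiments per treatment, which the deposited table gives only as their mean, and each deficient strain was sampled once per treatment. A quantitative PCR plate read 84 genes of the Toll-like receptor (TLR) pathway and 5 housekeeping genes, and every level is a delta-Ct value, in cycles, against the mean of *Hprt1*, *Hsp90ab1* and *Gapdh*. A difference of 1 cycle is a 2-fold difference in transcript level. No value used here has a replicate error, no difference between treatments or strains was tested, and "higher" and "lower" describe these pooled samples only. A reading above 35 cycles was set to 35, so a gene at that cap has only an upper limit on its level.

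The reference genes themselves crossed the detection threshold at different cycles, which sets how far down each column could see. Their mean Ct was 21.85 in wild-type Mock and at most 18.33 in wild-type R848. It was 19.90 in Mock and 19.37 in R848 for the pair labelled TLR7-deficient, and 22.57 in Mock and 20.07 in R848 for the pair labelled IFNAR-deficient. Mock readings therefore lay later than R848 readings by at least 3.52, by 0.53 and by 2.50 cycles. The number of pathway genes at the cap was 7 in wild-type Mock, 6 and 5 in TLR7-labelled Mock and R848, and 14 and 10 in IFNAR-labelled Mock and R848. It could not be identified in wild-type R848. The other housekeeping genes were also higher with R848 than with Mock relative to the 3 reference genes. *Actb*, encoding beta-actin, had log2 differences of 0.63 in wild type, 0.07 in the TLR7-labelled pair, where it turned below 0 with *Hprt1* alone or all 5 housekeeping genes as reference, and 1.60 in the IFNAR-labelled pair. *Gusb*, encoding beta-glucuronidase, had log2 differences of 1.88, 0.47 and 1.5. Among the reference genes, *Hprt1* differed by 0.28, 0.17 and 0.40, *Hsp90ab1* by -0.52, -0.13 and -0.40, and *Gapdh* by 0.23, -0.03 and 0.00.

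**Figure D1:**
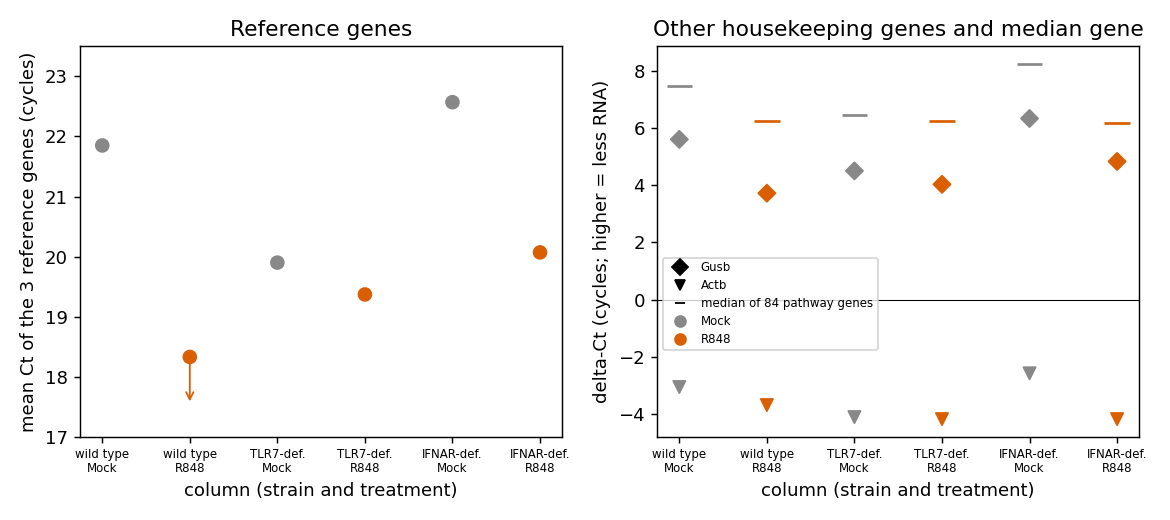
Left, mean Ct of the 3 reference genes (cycles) in each of the 6 columns, with an arrow where only an upper limit is known. Right, delta-Ct (cycles) of *Gusb*, *Actb* and the median of 84 pathway genes in the same columns, where a higher value is less RNA. Mock columns of wild type (21.85) and of the IFNAR-labelled strain (22.57) had the latest reference genes, and their median pathway gene lay at 7.47 and 8.23 cycles against 6.18 to 6.45 in the other 4 columns.

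*Tlr7*, the gene that encodes the receptor of R848, was read in every column. Its delta-Ct was 12 in wild-type Mock and 9.47 in wild-type R848. In the columns labelled TLR7-deficient it was 9.20 in Mock and 9.33 in R848, a level above that of wild-type Mock. In the columns labelled IFNAR-deficient it was 10.43 and 8.23. The position of the PCR product relative to the deleted part of the gene is not given in the sources used here, so the reading does not check the strain. No gene of the interferon receptor was on the plate, and the IFNAR label could not be checked either.

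The wild-type comparison asked what sustained TLR7 stimulation does to the pathway in spleen. Of 84 genes, 32 were at least 2-fold higher with R848 and 11 were at least 2-fold lower. Another 4 read lower with Mock at the cap, which leaves their direction open. The highest ratios were those of *Tlr4*, the lipopolysaccharide receptor (23.9-fold), *Hmgb1*, a chromatin protein that acts as a danger signal outside the cell (20.1-fold), *Il10*, an anti-inflammatory cytokine (18.8-fold), and *Eif2ak2*, the interferon-inducible kinase PKR (14.2-fold). The lowest among genes of known direction were *Cd80*, a co-stimulatory ligand (3.92-fold lower), and *Ripk2*, a kinase of NOD receptor signalling (3.41-fold lower).

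Receptors and their proximal signalling made up much of the higher group in wild type. Of 9 Toll-like receptors, 6 were at least 2-fold higher, 2 were within 2-fold and *Tlr5* had an open direction. Besides *Tlr4*, these were *Tlr1* (8.75-fold), *Tlr7* and *Tlr3* (5.78-fold each), *Tlr6* (4.53-fold) and *Tlr9* (2.04-fold), the last falling short of 2-fold under every scaling tried other than *Hsp90ab1* alone. In wild-type Mock *Tlr3* and *Tlr7* (12 each) and *Tlr6* (12.25) had delta-Ct values close to the cap of 13.15. These means may include a capped experiment, so the 3 ratios are less certain. The median log2 difference of the list was 2.18, at percentile 99.0 of 10000 random lists of the same size from the plate. Endosomal receptors for nucleic acids had 3 of 4 members higher, *Tlr9* included (median 1.78, percentile 92.2) and surface receptors 3 of 5 (median 2.18, percentile 95.7). Of 16 adaptors and proximal signalling genes, 8 were higher, 2 lower and 1 open (percentile 90.7). The higher ones included *Traf6*, the ubiquitin ligase downstream of MyD88 (8.17-fold), *Tollip*, an inhibitor of TLR signalling (8.46-fold), *Myd88*, the common TLR adaptor (5.58-fold), and *Tirap*, its bridging adaptor (5.21-fold). The lower ones were *Ripk2* and *Btk*, a kinase of B-cell receptor signalling (2.97-fold lower). With 5 housekeeping genes as reference or after centring on the median gene, 5 adaptors were higher and the same 2 lower. *Irak1* was at the cap in Mock and its direction was open. Of 4 inhibitors of TLR signalling, *Tollip*, *Il10* and *Tnfaip3* (4.23-fold) were higher and *Nfkbia*, the inhibitor of NF-kB, was 2.97-fold lower (median 2.58, percentile 99.0).

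Interferon-inducible genes were mostly higher in wild type, with 5 of 6 members at least 2-fold up (percentile 99.7). Besides *Eif2ak2*, they were *Tlr3*, *Tlr7*, *Myd88* and *Irf1*, an interferon-response transcription factor (3.81-fold). The exception was *Cxcl10*, a chemokine for activated T cells, with a log2 difference of -0.27, or 0.25 with *Hsp90ab1* alone as reference. This list shares *Tlr3*, *Tlr7* and *Myd88* with the lists above and is not separate evidence. *Ifnb1*, encoding interferon beta, was at the cap in Mock and its direction was open. In the MAPK, JNK and AP-1 pathway 6 of 10 genes were higher and none of the 10 was 2-fold lower (median 1.38, percentile 94.4), among them *Jun* (5.58-fold), *Mapk9* (4.86-fold) and *Mapk8* (3.81-fold). The NF-kB pathway had 2 of 11 genes higher, *Nfkb1* (5.03-fold) and *Tnfaip3*, and 1 lower, *Nfkbia* (percentile 31.6). Its median of 0.18 turned below 0 with *Hprt1* or *Gapdh* alone, with 5 housekeeping genes and after centring.

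Cytokines were more often lower than higher in wild type, an imbalance that did not hold under every scaling. Of 14 cytokines and chemokines, only *Il10* and *Il1a* (2.43-fold) were at least 2-fold higher, 5 were lower and 2 were open. The lower ones were *Il2*, a T-cell growth factor (2.97-fold lower), *Csf2* and *Lta* (2.58-fold lower each), *Il12a* (2.41-fold lower) and *Il6* (2.17-fold lower). In wild-type Mock *Il1a* (12.70), *Il6* (12.50) and *Csf2* (12.30) had delta-Ct values close to the cap of 13.15. A capped experiment within the mean would leave the direction of *Il6* or *Csf2* open. The list stood at percentile 0.395 of random lists, and at 2.87 with its open members left out. With *Hsp90ab1* alone as reference only *Il2* of the 5 was still 2-fold lower, and the median of members of known direction turned from -0.20 to 0.33. Log2 differences of the inflammatory cytokines *Tnf*, *Ifng* and *Il1b* were 0.43, 0.38 and 0.33, all within 2-fold, and turned to -0.07, -0.12 and -0.17 with 5 housekeeping genes as reference. *Csf3* was at the cap in Mock. *Tradd*, an adaptor of the TNF receptor (2.68-fold lower), and *Cebpb*, a transcription factor of myeloid cells (2.58-fold lower), completed the named genes.

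Lists for the cell types of a whole spleen were small in wild type. T and NK cell products had 2 of 3 genes lower (*Il2* and *Lta*; median -1.37, percentile 4.25). B cell-associated genes had 1 of 3 lower (*Btk*; median -0.97, percentile 8.74). *Cd86* was 2-fold lower too with *Hprt1* or *Gapdh* alone, with 5 housekeeping genes and after centring. Monocyte, macrophage and neutrophil markers had 3 of 7 higher (*Cd14*, *Clec4e* and *Tlr4*) and 1 open (median 0.53, percentile 60.5). Stromal genes had 1 of 3 higher (*Ppara*; percentile 60.8), co-stimulation 1 of 2 lower (*Cd80*), accessory and pattern-recognition molecules 3 of 9 higher (*Cd14*, *Clec4e* and *Hmgb1*; percentile 33.9), and stress genes 1 of 4 higher (*Jun*; percentile 33.6). With 5 housekeeping genes as reference 1 myeloid marker, 1 accessory molecule and no stromal gene were 2-fold higher, and *Hspd1* was 2-fold lower. Scaling moved the balance of higher to lower genes, cap-limited genes included, from 32 and 15 to 39 and 8 with *Hsp90ab1* alone as reference, to 22 and 21 with all 5 housekeeping genes and to 23 and 19 after centring on the median gene, whose log2 difference was 0.41. With the TLR7-labelled Mock column in place of wild-type Mock, an alternative chosen after seeing the data, the counts were 15 higher and 27 lower.

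**Figure D2:**
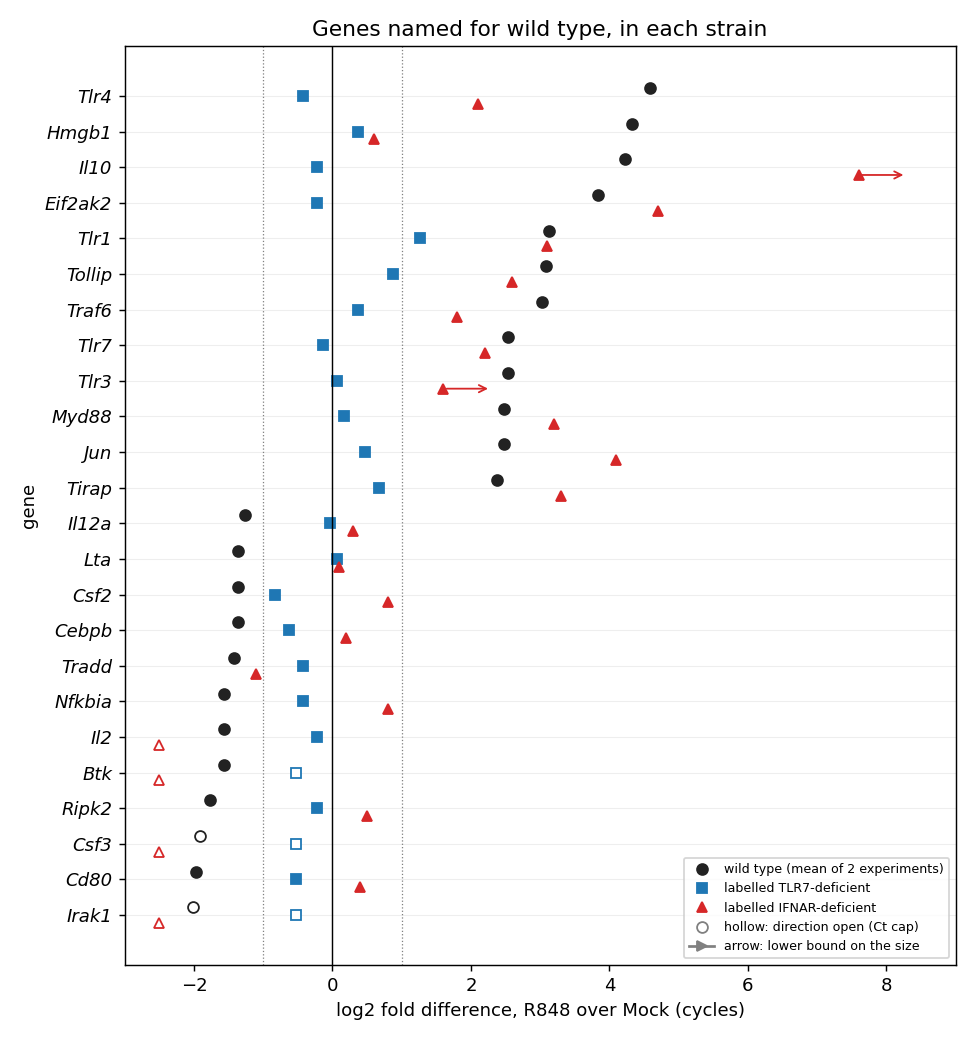
Log2 fold difference of R848 over Mock (cycles) for the 24 genes named for wild type, with 1 point per strain. Hollow points have an open direction because of the Ct cap, arrows mark lower bounds, and dotted lines mark 2-fold. In the TLR7-labelled pair the named genes of known direction lay between -0.83 (*Csf2*) and 1.27 (*Tlr1*), while in the IFNAR-labelled pair *Il10* was at least 7.60 and *Eif2ak2* was 4.70.

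The pair labelled TLR7-deficient asked whether the response to R848 needs its receptor. With R848, 4 of 84 genes were at least 2-fold higher and 3 were at least 2-fold lower. *Cd14*, the lipopolysaccharide co-receptor of myeloid cells, was at least 662-fold higher and *Ccl2*, a monocyte chemokine, was 43.1-fold lower. The others were *Map2k3* (2.58-fold), *Tlr1* (2.41-fold) and *Ptgs2*, encoding cyclooxygenase-2 (2.25-fold), which were higher, and *Casp8*, encoding an apoptosis-initiating protease (2.35-fold lower), and *Hspa1a*, encoding a heat-shock protein (2.19-fold lower). *Hspa1a* had delta-Ct values of 14 in Mock and 15.13 in R848, close to the caps of 15.10 and 15.63, so its ratio is less certain. The genes high in wild type had log2 differences of -0.43 (*Tlr4*), 0.37 (*Hmgb1*), -0.23 (*Il10*), -0.23 (*Eif2ak2*), 0.87 (*Tollip*), 0.37 (*Traf6*), -0.13 (*Tlr7*), 0.07 (*Tlr3*), 0.17 (*Myd88*), 0.47 (*Jun*) and 0.67 (*Tirap*) here. Among the genes low in wild type, *Cd80* stood at -0.53, *Ripk2* and *Il2* at -0.23, *Nfkbia* and *Tradd* at -0.43, *Cebpb* at -0.63, *Csf2* at -0.83 and *Lta* at 0.07.

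By list, the TLR7-labelled pair had 1 of 9 Toll-like receptors, 1 of 10 MAPK, JNK and AP-1 genes and 1 of 7 myeloid markers at least 2-fold higher. It had 1 of 16 adaptors, 1 of 14 cytokines and chemokines and 1 of 4 stress genes 2-fold lower. None of 6 interferon-inducible genes, 11 NF-kB genes, 4 inhibitors, 3 T and NK cell products or 3 stromal genes lay 2-fold away. Of 3 B cell-associated genes none did, with *Btk* open. The MAPK list had a median log2 difference of 0.42 (percentile 99.4) and the interferon-inducible list 0.07 (percentile 49.3). Cytokines and chemokines had a median of -0.23 (percentile 1.85, or 9.915 among lists matched on mean delta-Ct), or -0.13 (percentile 5.90) with the open members left out, and 1 of 14 was 2-fold lower, *Ccl2*. *Tlr9* differed by 0.37, *Irf1* by 0.27, *Cxcl10* by 0.07, *Il6* and *Tnf* by 0.27 each, *Ifng* by -0.23, *Il12a* by -0.03 and *Il1b* by -0.43, while *Ifnb1* and *Irak1* were at the cap. Values of 0.07 in this pair turned below 0 with *Hprt1* alone or 5 housekeeping genes. *Cd14*, *Ccl2* and *Casp8* lie in the first 4 wells of the plate, where the deficient strains depart most from wild type. Without those wells, an alternative chosen after seeing the data, 3 genes were higher and 1 lower (*Hspa1a*, close to the cap). With *Hsp90ab1* alone as reference the counts were 7 and 3.

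The pair labelled IFNAR-deficient asked how far the response runs through type I interferon signalling. Of 84 genes, 45 were at least 2-fold higher with R848, 2 were at least 2-fold lower and 9 read lower with an open direction. *Il10* was at least 194-fold higher, *Ccl2* at least 111-fold, *Cxcl10* 45.3-fold, *Eif2ak2* 26.0-fold, *Jun* 17.1-fold, *Tnf* 14.9-fold, *Il6* at least 13.9-fold and *Ticam1*, the adaptor of TLR3, 13.0-fold. *Cd14* was at least 111-fold lower and *Tradd* 2.14-fold lower. *Ccl2* and *Cd14* lie in the first 4 wells, where misplaced or failed readings are not excluded.

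All 6 interferon-inducible genes were at least 2-fold higher in this pair (median log2 difference 2.70, percentile 96.7), including *Myd88* (9.19-fold), *Tlr7* (4.59-fold), *Irf1* (2.64-fold) and *Tlr3* (at least 3.03-fold). Of 9 Toll-like receptors 8 were higher, the exception being *Tlr5* at the cap, with *Tlr9* at 8-fold, *Tlr1* at 8.57-fold and *Tlr4* at 4.29-fold (percentile 91.9). After centring on the median gene 4 of the 8 were still 2-fold higher (median 1.05). Adaptors had 9 of 16 higher and 3 open, with log2 differences of 3.30 for *Tirap*, 2.60 for *Tollip* and 1.80 for *Traf6*. The MAPK, JNK and AP-1 pathway had 7 of 10 higher, the NF-kB pathway 6 of 11 and inhibitors 3 of 4. After centring on the median gene the adaptors of known direction had 6 higher and 1 lower (*Fadd*). The MAPK list then had 3 higher, the NF-kB list 2 higher and 1 lower (*Nfkbil1*), and inhibitors 3 higher. Cytokines and chemokines had 8 of 14 higher and 3 open, with *Ifng* at 2.30-fold and *Il1b* at 2.14-fold. *Il12a* differed by a log2 value of 0.30. *Ifnb1*, *Irak1* and *Csf3* were at the cap in both columns. Myeloid markers had 5 of 7 higher, 1 lower (*Cd14*) and 1 open. With *Hprt1* alone or 5 housekeeping genes 3 myeloid markers were higher, and after centring 1. T and NK cell products had 1 of 3 higher (*Ifng*), and B cell-associated genes had none of 3 higher or lower and *Btk* open. Stromal genes had 2 of 3 and stress genes 2 of 4 higher, each with 1 open. After centring, no stromal gene and no T and NK cell product of known direction was 2-fold higher. Cytokines then had 5 higher, and *Lta* and the stress gene *Hspd1* were 2-fold lower. Genes high in wild type that were below 2-fold here included *Hmgb1* (log2 difference 0.60). Of the 11 genes low in wild type only *Tradd* was 2-fold lower here, *Il6* was higher, and *Il2* and *Btk* were open. *Cd80* stood at 0.40, *Ripk2* at 0.50, *Nfkbia* and *Csf2* at 0.80, *Cebpb* at 0.20 and *Lta* at 0.10, and these, *Hmgb1* and *Il12a* turned below 0 after centring on the median gene. These differences stand on a Mock column whose reference genes came up 2.50 cycles later than those of R848. The median gene of the plate was itself 1.25 higher on the log2 scale. After centring on it, 23 genes were higher and 18 lower in place of 45 and 11 with cap-limited genes included, and *Ifng* (-0.05), *Il1b* (-0.15) and the median of the cytokine list (-0.10) turned below 0. Without the 3 open cytokines at the cap that median stayed above 0, at 1.90 before and 0.65 after centring. With the TLR7-labelled Mock column as the control, 6 genes were at least 2-fold higher and 8 lower.

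Responses were then set against each other between strains, where the values of *Ccl2* and *Cd14* again come from the first 4 wells. The log2 difference in wild type exceeded that in the TLR7-labelled pair by more than 1 for 27 genes and fell short of it by more than 1 for 13, of which 8 had a known direction. The largest excesses were those of *Ccl2* (5.31), *Tlr4* (5.01), *Il10* (4.46), *Eif2ak2* (4.06), *Hmgb1* (3.96), *Traf6* and *Tlr7* (2.66 each) and *Tlr3* (2.46). The value for *Ccl2* comes from a high level in TLR7-labelled Mock (delta-Ct 4.7, against 10.13 in R848), since *Ccl2* stood at 9.8 and 9.92 in wild type. On the log2 scale, TLR7-labelled R848 lay near wild-type R848 for *Il10* and *Tlr7* (0.14 each) and *Traf6* (-0.41). It was lower for *Tlr3* (-0.96), *Hmgb1* (-1.01), *Eif2ak2* (-2.56) and *Tlr4* (-2.71). TLR7-labelled Mock lay above wild-type Mock for *Il10* (4.6), *Hmgb1* (2.95), *Tlr7* (2.8), *Tlr4* (2.3) and *Traf6* (2.25). It was 2.83-fold higher for *Eif2ak2* and *Tlr3*. Most of the excess of *Il10*, *Tlr7*, *Traf6* and *Hmgb1* thus lay between the Mock columns. The wild-type response fell short most for *Cd14* (-8.24, a bound), *Ripk2* (-1.54), *Cd80* and *Lta* (-1.44 each), *Il6* (-1.39), *Il2* (-1.34), *Il12a* (-1.24) and *Nfkbia* (-1.14). Of the 32 genes higher in wild type, 3 were also higher among the 4 in the TLR7-labelled pair, where independent lists would share 1.52 (Fisher's exact test, two-sided, p = 0.152). The counts of larger and smaller wild-type responses became 36 and 6 with *Hsp90ab1* alone, 21 and 20 with 5 housekeeping genes and 20 and 20 after centring.

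Against the IFNAR-labelled pair the wild-type response was larger by more than 1 for 8 genes, 4 of known direction, and smaller for 35, 34 of known direction. It was larger for *Cd14* (7.93, a bound), *Hmgb1* (3.73), *Tlr4* (2.48) and *Traf6* (1.23), and next came *Fadd* (0.88), *Nr2c2* (0.83), *Mapk8ip3* (0.78) and *Mapk9* (0.58). It was smaller for *Ccl2* (-6.92, a bound), *Cxcl10* (-5.77), *Il6* (-4.92, a bound), *Tnf* (-3.47), *Il10* (-3.37, a bound), *Elk1*, a transcription factor of the MAPK pathway (-2.82), and *Cd80* and *Nfkb2* (-2.37 each). Of the 32 genes higher in wild type, 25 were also among the 45 higher in the IFNAR-labelled pair, where independent lists would share 17.1 (Fisher's exact test, two-sided, p = 0.000624). Genes of 1 pathway are not independent, so that p describes this plate only. After centring each comparison on its median gene the counts were 22 larger and 18 smaller.

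Across genes of known direction, wild-type log2 differences correlated with those of the TLR7-labelled pair at Pearson's r = 0.204 and Spearman's rho = 0.515 (78 genes, permutation p = 0.0738 and 1e-05). They correlated with those of the IFNAR-labelled pair at r = 0.394 and rho = 0.530 (74 genes, permutation p = 0.00053 and 1e-05). Between the deficient pairs r was -0.519 and rho 0.219 (75 genes, permutation p = 0.00098 and 0.06003). Adjusted by Benjamini-Hochberg over the family of 3, the permutation p-values of r were 0.0738, 0.00147 and 0.00147, and those of rho were 2e-05, 2e-05 and 0.06003. The value 1e-05 is the smallest that 100000 permutations can give, and genes are not independent replicates. The negative r rested on the first 4 wells, and without them the 3 values of r were 0.463, 0.546 and 0.234.

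**Figure D3:**
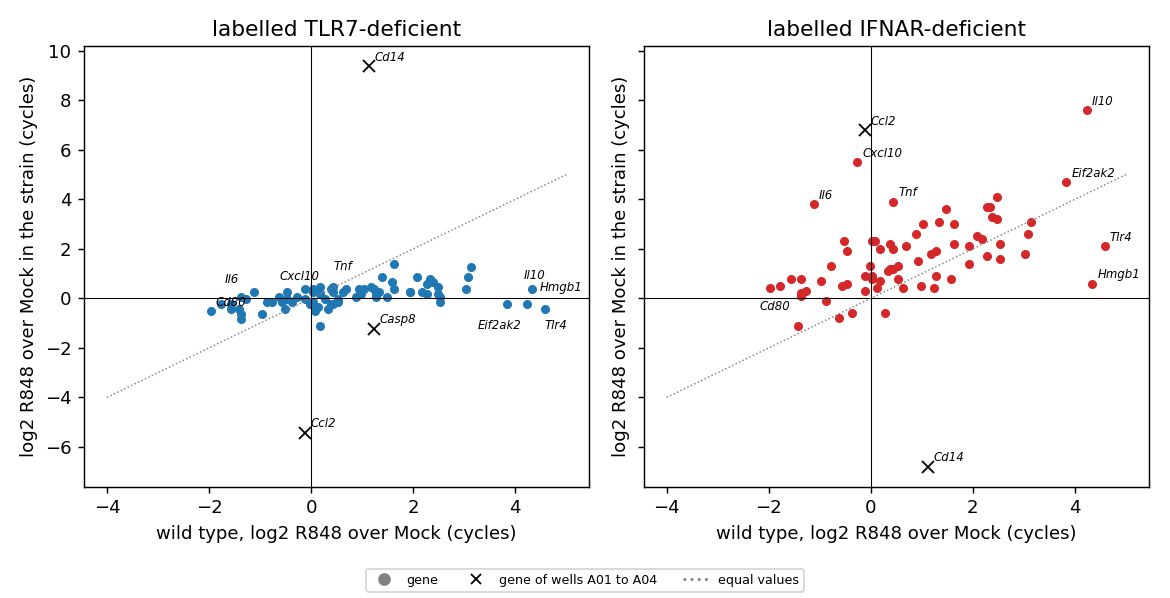
Log2 fold difference of R848 over Mock (cycles) in wild type (x axis) against the strain labelled TLR7-deficient (left) or IFNAR-deficient (right), with 1 point per gene of known direction in both and bounds drawn at their limit. Crosses are genes of the first 4 wells and the dotted line marks equal values. In the left panel most genes lie near 0 on the y axis (median 0.07 over all 84), and in the right panel most lie above it (median 1.25).

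Mock columns were compared across strains to show the levels without R848, after 7 days of PBS. The tables were normalized separately, each to its own reference genes. Relative to wild-type Mock, the TLR7-labelled Mock column had 41 genes at least 2-fold higher and 4 lower of known direction. *Ccl2* was 34.3-fold higher, *Il10* 24.3-fold, *Clec4e*, a myeloid pattern-recognition receptor, 15.5-fold, *Jun* 9.51-fold, *Il1a* 8.57-fold, *Myd88* 8.28-fold, *Il6* 8-fold, *Hmgb1* 7.73-fold, *Tlr7* 6.96-fold and *Tlr4* 4.92-fold. *Btk* was at least 2048-fold lower, *Cd14* at least 495-fold, *Casp8* 24.3-fold and *Il2* 9.51-fold. The genes *Btk*, *Casp8*, *Ccl2* and *Cd14* lie in the first 4 wells, where misplaced or failed readings are not excluded in any strain. Toll-like receptors had a median log2 difference of 1.75 (percentile 96.2) and myeloid markers 1.90 (percentile 96.8). Accessory and pattern-recognition molecules had the lowest percentile of the lists (0.505, median -0.55), and B cell-associated genes had a median of -0.55 (percentile 6.63). The accessory median counts *Hspa1a*, open because wild-type Mock was at the cap, and *Cd14* of the first 4 wells. Its low percentile rests partly on these readings. Of the other members, *Clec4e*, *Hmgb1*, *Pglyrp1* (0.70) and *Muc13* (0.45) read higher on the log2 scale. *Hspd1* (-0.85), *Ly96* (-0.60) and *Ly86* (-0.55) read lower. In the IFNAR-labelled Mock column 4 genes were higher and 26 lower than in wild-type Mock. The higher ones were *Hmgb1* (7.57-fold), *Tlr7* (2.97-fold), *Il1a* (2.25-fold) and *Fadd* (2.03-fold). *Btk* was at least 322-fold lower, *Casp8* at least 86.2-fold, *Cxcl10* 11.6-fold, *Mapk8* 5.39-fold and *Tnf* 3.68-fold. The interferon-inducible list had a median of -0.18 (percentile 66.1), which lay 0.15 above the median gene.

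The balance between Mock columns depended on scaling. For the TLR7-labelled strain 41 higher and 8 lower, cap-limited genes included, became 31 and 12 with *Hprt1* alone, 28 and 13 with 5 housekeeping genes and 15 and 16 after centring on the median gene, whose log2 difference was 0.93. For the IFNAR-labelled strain 4 and 26 became 16 and 20 with *Hsp90ab1* alone, 8 and 20 with 5 housekeeping genes and 18 and 20 after centring.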

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

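All tests in this part were chosen after the values had been seen, and none of the differences between strains below was itself tested. They are listed because the treated sample lay at least 2-fold to opposite sides of Mock in 2 strains. *Casp8* was 1.23 higher on the log2 scale with R848 in wild type and -1.23 in the TLR7-labelled pair, a difference of 2.46. *Cd14* was 1.13 in wild type and at most -6.80 in the IFNAR-labelled pair, a difference of at least 7.93. *Il6* was -1.12 in wild type and at least 3.80 in the IFNAR-labelled pair, a difference of -4.92 as a bound. Its wild-type Mock mean (delta-Ct 12.50) lay close to the cap of 13.15. A capped experiment within that mean would leave the wild-type direction of *Il6* open. Between the deficient pairs *Ccl2* stood at -5.43 with TLR7 named and at least 6.80 with IFNAR named (-12.23, a bound). *Cd14* stood at 9.37 and -6.80, both bounds (16.17).

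Of these genes, *Casp8*, *Ccl2* and *Cd14* occupy wells A02 to A04, next to *Btk* in A01. Set against the mean of the wild-type columns, the 4 genes with the largest departure in any deficient column were exactly these (4 of 4), which restates what drew attention to the wells and is no evidence for a cause. *Btk* lost at least 7.545 cycles in every deficient column while *Ly86* and *Cd86* lost at most 1.245. *Ly86* and *Cd86* are listed as B cell-associated, not as specific to B cells, so a loss of B cells is not excluded. A loss of monocytes, macrophages and neutrophils is argued against by other myeloid genes. *Cd14* lost at least 9.345 cycles in TLR7-labelled Mock and IFNAR-labelled R848. The largest value there among *Clec4e*, *Tlr2*, *Tlr4*, *Pglyrp1* and *Il1b* was -0.01. Misplaced or failed readings in these wells, in any of the strains, and a change in each gene's own regulation both stay open.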

How the results depend on the processing

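No paired analysis was possible because the values used here give the 2 wild-type experiments only as 1 mean, although their samples form 2 pairs, and each deficient strain has 1 pair. For the same reason leaving out an experiment, the arithmetic mean of folds, a linear model without moderation and limma with pooled spread were not run. Leaving out the first 4 wells, counting known directions only, the TLR7-labelled Mock control and matched random lists were chosen after seeing the data. So were list medians and counts over known directions under each scaling. Of 158 counts recomputed for the 14 main counts, 109 stayed within 1.5 times and 49 did not. The balance of 4 comparisons turned over. With TLR7-labelled Mock as control more genes were lower than higher in wild type (15 and 27) and in the IFNAR-labelled pair (6 and 8). After centring, larger wild-type responses outnumbered smaller ones against the IFNAR-labelled pair (22 and 18), and TLR7-labelled Mock had fewer genes above than below wild-type Mock (15 and 16). The cause was not tested, except that a higher threshold or fewer genes lowers a count by construction. Against matched random lists the wild-type percentiles were 98.4 for Toll-like receptors, 99.9 for interferon-inducible genes, 1.675 for cytokines and 51.3 for stress genes, in place of 99.0, 99.7, 0.395 and 33.6. *Gapdh* or *Hprt1* alone moved none of the 14 beyond 1.5 times.

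With *Hsp90ab1* alone, wild type had 8 genes lower, the TLR7-labelled pair 7 higher, 6 genes had a smaller response in wild type than in that pair, and IFNAR-labelled Mock had 16 genes above wild-type Mock. With 5 housekeeping genes, 20 genes had a smaller response in wild type than in the TLR7-labelled pair, TLR7-labelled Mock had 13 below wild-type Mock and IFNAR-labelled Mock 8 above it. After centring on the median gene, the IFNAR-labelled pair had 23 higher and 18 lower. Then 20 genes had a smaller response in wild type than in the TLR7-labelled pair, and 22 a larger and 18 a smaller one than in the IFNAR-labelled pair. TLR7-labelled Mock had 15 above and 16 below wild-type Mock, and IFNAR-labelled Mock 18 above. Centring also reversed 3 values of the IFNAR-labelled pair, the cytokine list's median (-0.10), *Ifng* (-0.05) and *Il1b* (-0.15). The median reversed because 3 open members at the cap were counted, and was 0.65 without them. Another 59 recomputed values, of genes or list medians under 2-fold, had the opposite sign under a scaling.

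Without genes at the cap, the IFNAR-labelled pair had 1 lower, 7 genes had a smaller response in wild type than in the TLR7-labelled pair, 3 a larger one than in the IFNAR-labelled pair, and TLR7-labelled Mock had 2 below wild-type Mock. Without genes above Ct 33, wild type had 9 lower and the IFNAR-labelled pair 1. Then 5 had a smaller response in wild type than in the TLR7-labelled pair, 3 a larger one than in the IFNAR-labelled pair, 1 was below wild-type Mock in TLR7-labelled Mock and 2 were above it in IFNAR-labelled Mock. With known directions only, the IFNAR-labelled pair had 2 lower, the smaller wild-type responses numbered 8 against the TLR7-labelled pair, the larger ones 4 against the IFNAR-labelled pair, and TLR7-labelled Mock had 4 below wild-type Mock. Without the first 4 wells the TLR7-labelled pair had 1 lower and its Mock 5 below wild-type Mock. With TLR7-labelled Mock as control, wild type had 15 higher and 27 lower and the IFNAR-labelled pair 6 higher.

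At 1.5-fold the TLR7-labelled pair had 10 higher and 6 lower, 20 genes had a smaller response in wild type than in that pair, 14 a larger one than in the IFNAR-labelled pair, TLR7-labelled Mock had 13 below wild-type Mock and IFNAR-labelled Mock 19 above. At 3-fold wild type had 21 higher and 5 lower and the TLR7-labelled pair 1 and 1. Then 2 had a smaller response in wild type than in the TLR7-labelled pair, 22 a smaller one than in the IFNAR-labelled pair, TLR7-labelled Mock had 23 above wild-type Mock, and IFNAR-labelled Mock 1 above and 13 below. Late reference genes limit IFNAR-labelled Mock most, where 14 genes were at the cap.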

Other observations

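All tests in this part were chosen after the values had been seen. Levels across the 6 columns show which genes set the wild-type ratios. *Hmgb1* had a delta-Ct of 10.55 in wild-type Mock and between 6.22 and 7.63 in the other 5 columns. *Eif2ak2* was at 5.97 and 4.13 in the R848 columns of wild type and the IFNAR-labelled strain, and between 8.30 and 9.80 in the rest. *Cxcl10* lay between 0.03 and 2.27 except in IFNAR-labelled Mock (5.53). *Il6* was at 12.50 and 13.62 in the wild-type columns, at the cap in IFNAR-labelled Mock, and between 8.63 and 9.50 in the remaining 3. *Csf3*, *Ifnb1*, *Irak1* and *Tlr5* were at the cap in every column where it could be identified.

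Among R848 columns, each deficient strain had 25 genes of known direction at least 2-fold above wild type, and 12 (TLR7-labelled) or 13 (IFNAR-labelled) below it. *Il6* was 21.0-fold higher in the TLR7-labelled and 31.8-fold higher in the IFNAR-labelled R848 column, and *Clec4e* 5.82-fold and 8.22-fold. *Tlr4* and *Eif2ak2* were 6.54-fold and 5.90-fold lower in the TLR7-labelled R848 column than in that of wild type. Over the 80 genes outside the first 4 wells, delta-Ct in IFNAR-labelled R848 correlated with TLR7-labelled Mock at r = 0.973, with TLR7-labelled R848 at 0.972 and with its own Mock at 0.852. The TLR7-labelled columns correlated with each other at 0.992. Over all 84 genes, however, TLR7-labelled Mock correlated better with IFNAR-labelled R848 (0.969) than with its own R848 (0.939). An exchange of columns between the deficient-strain tables is not excluded by these values and would alter what each of their folds means. Among genes of known direction, values identical in both columns within 0.006 cycles were found for *Tlr3* and *Tlr7* in wild type, and for *Mapk8* and *Tlr6* and for *Nfkbil1* and *Tbk1* in the TLR7-labelled pair.

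Wild-type and IFNAR-labelled Mock were together the lowest of the 6 columns for 42 of 81 genes, where 5.4 would fall to each of 15 pairs if all were alike and the next pair had 10. A single factor common to all genes and a broad response of the pathway cannot be told apart by centring. The pair was lowest together for 8 of 83 genes after each column was centred on its median gene, which takes away either. The housekeeping genes *Actb* and *Gusb*, which are not pathway genes, were lowest in the same columns before centring. A common factor would give this, but 2 genes do not settle it. Gene-specific loss of signal in columns with late reference genes stays open, since wild-type differences correlated across 72 genes with TLR7-labelled over IFNAR-labelled Mock, which share no column with them, at only r = 0.322 (permutation p = 0.00563), against -0.290 for the R848 columns. The criterion for r was raised after r had been seen, and under the first one this r would have counted in favour of such a loss. The absence of a response without TLR7 stays open too, since the position of TLR7-labelled Mock between wild-type Mock and R848 (0.7426, or 0.46 after centring) was taken over 29 genes chosen by their wild-type Mock and R848 values and decides nothing.

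Interferon-inducible genes were higher with R848 in mice labelled as lacking the type I interferon receptor. A single factor between the columns is argued against as the whole cause, since the 6 genes kept a median log2 difference of 1.45 after centring (lower quartile 0.50), with 3 of 6 still at least 2-fold higher, *Cxcl10*, *Eif2ak2* and *Myd88*. A lower level in IFNAR-labelled Mock stays open as a partial explanation for some members only. The list's median against wild-type Mock lay 0.15 above that of all genes, and members went both ways. *Cxcl10* (-3.53), *Tlr3* (at most -0.43) and *Irf1* (-0.38) read lower than in wild-type Mock. *Myd88* (0.02) read level, and *Eif2ak2* (0.97) and *Tlr7* (1.57) higher. Against wild-type R848, IFNAR-labelled R848 stood at 2.24 for *Cxcl10*, 1.84 for *Eif2ak2*, 1.24 for *Tlr7* and 0.74 for *Myd88*. It stood at -0.91 for *Irf1* and -1.36 for *Tlr3*. Induction through another route, such as interferon gamma, and an error in the strain label were not tested and may also apply.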
